A study of Mus musculus with 3 samples.

How the data were processed

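Cells were taken from the tail epidermis of mice with an EGFP and diphtheria toxin receptor reporter at the Lgr5 locus, at postnatal day 7, at postnatal day 30 and in adults. Per the labels' protocols, the skin was digested in trypsin overnight at 4°C, dead cells were excluded with Hoechst, and α6 integrin-positive, CD34-negative, EGFP-negative cells were sorted. The P7 and adult cells were sorted on a BD Influx and the P30 cells on a FACS Aria I at another site. Libraries were made with 10x Chromium 3' reagents, labelled as V2 chemistry for all 3 ages, and sequenced on an Illumina NovaSeq. The labels state 6000 cells loaded per channel. They also state 10338, 948 and 10920 cells, which equal the numbers of barcodes found, and 33179, 245972 and 30857 reads per cell at P7, P30 and adult. Median genes per barcode were 2290, 5049.5 and 2309, against stated values of 2290, 5050 and 2309. For each 100 reads stated there were 20.9, 10.5 and 26.8 UMIs. The step from overnight digestion to sorting can itself induce stress transcripts, and a 3' protocol counts the ends of polyadenylated transcripts only.

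The deposited matrices hold UMI counts per gene and barcode, whole numbers that were not normalised, for barcodes the authors had already called as cells. Per the file headers, Cell Ranger 3.0.2 made the P7 and adult matrices and Cell Ranger 3.1.0 the P30 matrix. The submitters' processing notes name Cell Ranger 3.0.2, Seurat 3.0.1 and the mm10 genome; no Seurat output was analysed here, and the gene annotation the authors counted against is not given in the sources used here. Each matrix has the same 31053 genes, and no other column of per-sample values was found (0). For P7 and adult the deposited regulon tables were used as well. They give a motif enrichment score and target genes per transcription factor, and an activity score (AUC) per cell for 306 factors in 10334 cells at P7 and 294 factors in 10915 cells of the adult, per the file headers. How the authors made these scores is not given in the sources used here; the layout is that of SCENIC, and the tables name rankings of the mm9 genome. An AUC depends on the regulons inferred in its own library, so scores were compared within a library only, as differences of means in SDs over cells.

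The choices in this paragraph were made before the data were examined, apart from those named as later. Barcodes with at least 1000 genes and at most 10% mitochondrial UMIs were kept, which left 9464 at P7, 659 at P30 and 10437 in the adult. The mitochondrial limit alone applied to 708, 260 and 328 barcodes and the gene limit to 733, 45 and 387. Doublets were scored with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 402 cells at P7 and 5 at P30 and was used there. In the adult it marked 1 cell, under the required 0.5%, so the 912 cells with the highest scores were removed, at 0.8% per 1000 barcodes. The barcodes of P7 and adult exceed the 6000 cells loaded per channel; if several channels were pooled, which the labels do not say, that rate is too high. Marked doublets had median UMI counts of 12777, 78278 and 12415.5. The cells left numbered 9062, 654 and 9525, with median depths of 6548.5, 33890.5 and 7449 UMIs and 2327, 5430.5 and 2305 genes. Each library was clustered on its own with 2000 variable genes, 30 principal components, 15 neighbours, Jaccard weights of shared neighbours and Leiden resolution 0.6 (leidenalg 0.10.2, seed 7). Clusters were named from fixed markers of 16 cell types. A name needed at least 3 detected markers and at least 0.4 of the type's markers above the other clusters by 0.25 on the log2 scale, and the 10 leading genes, each at 50 CPM or more, could not hold more markers of another type. A marker counted as detected at 20 CPM. That it, or a leading gene, also needed a UMI in 10% of the cluster's cells was set after the clusters had been seen.

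UMIs were summed over interfollicular basal-like and cycling keratinocyte-like cells per library (the basal class) and scaled to the total of the class (CPM). With 1 library per age no test was made; edgeR was used only for its TMM factors, an alternative scaling (1.00, 1.09 and 0.919 for P7, P30 and adult). Sums have exact Poisson and shares exact Clopper-Pearson intervals at 95%, and ratios an exact conditional binomial interval. These cover counting error only, since cells of a library are not replicates. A count of 0 was set to 3 counts as a bound. A rule of size took genes at 20 CPM or more in either library that were at least 2-fold apart. For 26 fixed gene lists, the median log2 ratio of members at 5 CPM or more was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The lists covered S phase, G2/M, basement membrane and hemidesmosome, early and late differentiation, immediate early response, heat shock, wound and alarm genes, interferon and antigen presentation, glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, Wnt, Notch, BMP and TGFβ, YAP targets, imprinted growth genes, fetal and juvenile growth, Hox, clock, tail scale and interscale, sex-linked, collagen and dermal matrix, antioxidant and xenobiotic, and senescence and cell cycle inhibitor genes. For P7 over adult 4 of the 26 lay above the central 95% of random lists and 3 below it, and for P30 over adult 6 and 4. The share of cells with G2/M transcripts was taken after thinning each cell to 4000 UMIs, with a threshold of 3 UMIs. Because that threshold also counted most differentiated-like cells, one of 20 UMIs was added after the data were seen.

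Genes were named by a fixed rule. Among genes at 50 CPM or more in either library it takes the 12 highest and 12 lowest ratios for P7 with adult and the 8 highest and 8 lowest for each P30 comparison. Mitochondrially encoded genes, ribosomal protein genes and their pseudogenes, Gm and Rik models, haemoglobins, Xist and Y-linked genes are left out of this part. The rule adds the 2 highest and 2 lowest members at 20 CPM or more of each list and the sorting markers Itga6, Cd34 and Lgr5. For regulons it adds 15 fixed factors and the 10 with the largest AUC difference per contrast and library. The 15 include Trp63, Klf4, Gata3, Grhl1, Grhl3, Sox9, Fos, Jun, Junb, Atf3, E2f1, E2f8, Myc and Irf7. Of these genes, those that matter most to a comparison are printed, and a few that the rule takes are not reported here. Coordinates are from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, matched by Ensembl identifier for 210 of 210 named genes. Transcript length is the median exonic length over a gene's protein-coding transcripts there, known for 99.1% of the genes compared at 20 CPM.

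Alternatives were a looser cell filter (500 genes, 20% mitochondrial), doublets kept, Leiden resolution 1.2, joint clustering, all kept cells, cells without G2/M transcripts, floors of 5 and 100 CPM, a list floor of 20 CPM, TMM factors, totals without mitochondrial and ribosomal protein genes, means of per-cell CPM, other thinning and thresholds, and stricter regulon overlap. After seeing the data, a wider basal class, basal-like clusters alone, cells below 20 G2/M UMIs and the subtraction of medians by transcript length (in all 3 comparisons) were added. The calculations were tested on data simulated for P7 and adult with 5292 genes. Of 50 genes each changed 3-fold, 4-fold and 8-fold, 100% were found at least 2-fold apart in the right direction, and of 50 changed 1.5-fold 0%. Of 5092 unchanged genes 0 were 2-fold apart. The simulated counts held Poisson counting error only, without differences between animals, sorts or library preparations. They check the calculations and do not show how often such differences would place a gene 2-fold apart. The ratio intervals held the true value for 95.3%, the Poisson intervals for 95.0% and the binomial intervals for 95.9%. Of 60 lists without a shift 3 lay outside the central 95%, and 20 of 20 shifted lists lay above it. Thinning gave a mean of 16.0 list UMIs where 16 were put in. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.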

Results

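Single-cell RNA sequencing measured the transcripts of cells sorted from mouse tail epidermis at 3 ages, with 1 library per age. The ages were postnatal day 7 (P7), postnatal day 30 (P30) and adult, whose age label gives a day above 60. The mice carried an EGFP reporter driven from the Lgr5 locus. Cells were gated as positive for α6 integrin, which basal keratinocytes carry towards the basement membrane, and as negative for CD34 and EGFP, which mark the hair follicle bulge. The source field of the adult sample names postnatal day 7, whereas its title and age field say adult, and those were followed. The P7 library held 10338 barcodes and 71679892 unique molecular identifiers (UMIs, each standing for a captured transcript). The P30 library held 948 barcodes and 25681489 UMIs, and the adult library 10920 barcodes and 90066204 UMIs. The median number of UMIs per barcode was 6382 at P7, 28198.5 at P30 and 7457 in the adult. Median mitochondrial shares were 3.24%, 7.33% and 3.07% of UMIs. The P7 and adult cells were sorted on the same type of instrument at one site and the P30 cells on another at a different site, so age and sort cannot be separated for P30. No barcode of the P30 library occurred in either other library, whereas the P7 and adult libraries had 162 in common. Because each age has n = 1 library, no difference was tested, no p-value is given, and intervals (95%) cover counting error only.

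Interfollicular basal-like and cycling keratinocyte-like cells together made up 50.9% of the 9062 P7 cells kept (49.9 to 52.0), 45.4% of the 654 P30 cells (41.5 to 49.3) and 38.8% of the 9525 adult cells (37.8 to 39.8). These cells are called the basal class. It comprised clusters 0, 3, 5, 6 and 11 of the P7 library, clusters 0, 4, 6 and 7 of P30 and clusters 1, 5, 6, 8, 9 and 13 of the adult, each library having been clustered on its own. Cells resembling differentiated interfollicular epidermis made up 10.9% of the P7 library (10.3 to 11.6), 14.2% of P30 (11.6 to 17.1) and 29.1% of the adult (28.2 to 30.0). Upper hair follicle-like cells were 5.11%, 6.88% and 13.2% in that order. Sebaceous gland-like cells were 4.38%, 2.75% and 2.27%. Bulge or outer root sheath-like cells were 7.13% of P7 and 1.21% of adult cells, and no P30 cluster took that name. In P30 cluster 1, left unnamed with 118 cells, the bulge and outer root sheath markers scored highest of all types. Clusters that could not be named held 21.1% of P7, 30.7% of P30 and 15.2% of adult cells, and their leading genes included Fst and Sostdc1 in P7 cluster 1, Krt17 and Postn in P30 cluster 1, and Dcn in P30 cluster 3 and adult cluster 0. Basal markers scored highest of all types in P7 cluster 1, P30 cluster 3 and adult cluster 0. With these added, the basal class would hold 68.0% of P7, 58.1% of P30 and 54.0% of adult cells. The basal class as used therefore leaves out many cells that score as basal. Cell cycle genes such as Cdkn3 and Cenpa led 1 basal-like cluster in each library, and Ccne2 and Ung led cluster 6 of the adult. Stress and immune genes also stood among the leading genes of named clusters, with Atf3 in P30 clusters 0 and 7, Il33 in the former, Ifi27l2a in the latter, Ccl2, Saa3 or Lcn2 in the sebaceous gland-like clusters, and Trbc2 in adult cluster 7. The leading genes of like-named clusters differed between libraries and the gate itself sets these shares, so they describe each library and no order of ages is read from them. With doublets kept, the differentiated-like share was 22.3% at P30 and 19.2% in the adult. At a finer clustering, upper hair follicle-like cells were 11.7%, 2.75% and 4.34%, and bulge or outer root sheath-like cells 2.89%, 3.21% and 1.21%. Clustered together without integration, the libraries stayed apart: the largest clusters held 3483 P7 with 4 adult cells and 3428 adult cells with no others, and 594 of the 654 P30 cells shared a cluster with 2 others.

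The markers of the sort were read first. Itga6, the gene of α6 integrin (ENSMUSG00000027111, GRCm38 chromosome 2, 71745616 to 71858416), had 164 CPM (UMIs of a gene scaled to the total of the class) in the basal class at P7, 348 at P30 and 186 in the adult. Cd34 had 2, 0 and 3 UMIs and Lgr5 7, 0 and 3 UMIs among 33690621, 10767790 and 30606466 UMIs of the basal class. Xist had 3, 1 and 2 UMIs, and the Y-linked Eif2s3y 76.1, 94.7 and 83.7 CPM.

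The summed transcripts of the G2/M list were higher in the P7 than in the adult basal class, but the median log2 ratio of its genes, 0.30, lay within random lists (percentile 70.0), beside 0.24 over all genes. The 52 genes of the G2/M list summed to 8436 CPM at P7 (8405 to 8467), 7577 at P30 (7525 to 7629) and 6692 in the adult (6663 to 6721). With the total taken without mitochondrial and ribosomal protein genes the sums were 10649, 11276 and 9354, so the place of P30 rests on the scaling. The 42 genes of the S-phase list summed to 3082, 2446 and 2479 CPM. After thinning to 4000 UMIs per cell, the fixed threshold of 3 G2/M UMIs counted 99.0% of P7, 88.8% of P30 and 95.5% of adult basal class cells. It also counted 97.2%, 78.0% and 89.5% of the differentiated-like cells. The threshold thus took in most cells of either class, and no cycling is read from these shares. At 20 or more UMIs, a threshold chosen after the data were seen, 38.1% of P7 cells (36.7 to 39.6), 32.5% of P30 cells (27.2 to 38.2) and 30.0% of adult cells (28.5 to 31.6) were counted. Among differentiated-like cells this threshold counted 0.316% at P7, 0 of 91 at P30 and 0.0372% in the adult. These low shares are no independent background. Cells rich in cycle transcripts were named as a class of their own, by markers such as Top2a and Mki67 that are also in the G2/M list. Gadl1 was a leading gene both of P7 cluster 11, which is cycling and in the basal class, and of differentiated-like P7 cluster 2. Median depths before thinning were 6685, 35063 and 7537 UMIs in the basal class and 8899, 36811 and 8641 in the differentiated-like cells. Thinning left out 234, 2 and 76 shallower cells, and 158, 15 and 98 cells lay within 2 UMIs of the threshold. Without thinning the shares were 50.3%, 88.6% and 42.9%. At 20 UMIs after thinning, the P7 interval of the basal class lay above the adult one, and the P30 interval overlapped both. In the interfollicular basal-like clusters alone the shares were 13.1% (11.9 to 14.3), 8.57% (4.88 to 13.7) and 10.4% (9.32 to 11.6). The basal class leaves out P7 cluster 1, P30 cluster 3 and adult cluster 0, so its shares also depend on which clusters could be named. No share was taken with those clusters added.

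**Figure D1:**
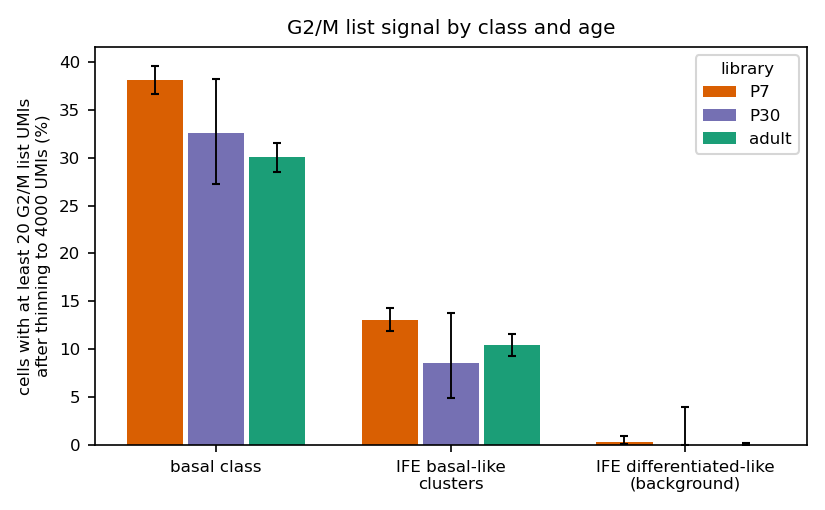
Percentage of cells with at least 20 G2/M UMIs after thinning to 4000 UMIs, by library and cell class, with exact binomial 95% intervals. The basal class stands at 38.1% (P7), 32.5% (P30) and 30.0% (adult), and the differentiated-like cells at or below 0.316%.

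The comparison of P7 with adult asks which transcripts differ between basal cells of growing and of adult tail skin. In the P7 library, imprinted growth genes, other genes of fetal and juvenile growth, and Hox genes were higher as groups. Clock genes, interferon and antigen-presentation genes, and antioxidant and xenobiotic genes were lower as groups. Peg3, a paternally expressed imprinted zinc-finger gene, was 285-fold higher at P7 and Krt24, a keratin, 115-fold lower. Of 5765 genes at 20 CPM or more in either library, 840 were at least 2-fold apart, 436 higher and 404 lower at P7. By this rule of size, which is no test, 51.9% were higher, against 35.0% with TMM factors and 32.0% with the total taken without mitochondrial and ribosomal protein genes, so the balance of directions rests on the scaling. The median log2 ratio over these genes was 0.24, and 0.12 and 0.09 under those 2 scalings. Each gene list is therefore set against 10000 random lists of the same size matched on mean expression, as a description of these libraries. Members named as highest or lowest of a list are chosen among those at 20 CPM or more in either library.

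All 10 measured members of the imprinted growth network were higher at P7, 7 of them by 2-fold or more, with a median log2 ratio of 2.43 (percentile 100). Peg3 (ENSMUSG00000002265, chromosome 7, 6703892 to 6730431) had 83.9 CPM at P7 (80.8 to 87.0) and 0.294 in the adult (0.134 to 0.558), a log2 ratio of 8.16 (7.23 to 9.29) that rests on 9 adult UMIs. It was 9.78 (7.93 to 12.83) among cells below 20 G2/M UMIs and 9.32 (7.77 to 11.60) in the basal-like clusters alone, with 2 and 3 adult UMIs. H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143), a maternally expressed imprinted long non-coding RNA, had 1451 CPM at P7 (1438 to 1464) and 13.2 in the adult (11.9 to 14.5), a 110-fold difference. The smallest differences of the list among genes at 20 CPM were those of Dcn (log2 0.75), which encodes the matrix proteoglycan decorin, and Ascl2 (0.80), a transcription factor. The basal class leaves out adult cluster 0, which Dcn leads; with the unnamed clusters that scored highest for basal markers added, Dcn had 108 CPM in both libraries. The median of the list was 2.62 in the interfollicular basal-like clusters alone, which still include clusters led by cycle genes, 2.85 in differentiated-like, 1.09 in upper hair follicle-like and 1.37 in sebaceous gland-like cells. The upper hair follicle-like cells were those of cluster 7 at P7 and mostly those of cluster 2 in the adult (1072 cells), whose leading genes Fst and Sostdc1 also led the unnamed cluster 1 of P7, so that class is not like with like. In the fetal and juvenile growth list 8 of 10 measured genes were higher at P7 (median 1.12, percentile 99.99), including Sox4, a progenitor transcription factor (120 against 20.9 CPM), and Igf2bp3, an RNA-binding protein of fetal tissues (82.8 against 20.6 CPM). Of 18 measured Hox genes, which record position along the body axis, 17 were higher at P7 and 7 by 2-fold or more (median 0.88, percentile 100). Hoxc10 (log2 2.49) and Hoxd10 (1.63) differed most, and Hoxd11 (0.07) and Hoxc13 (0.22) least.

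Of 17 measured circadian clock genes 15 were lower at P7, 12 of them by 2-fold or more, with a median log2 ratio of -2.77 (percentile 0). Bhlhe41, a transcriptional repressor of the clock, had 0.178 CPM at P7 against 24.7 in the adult, and Ciart, another repressor, 2.23 against 33.9. Rora (log2 -0.07) and Clock (-0.46) differed least. The list median was -2.46 in differentiated-like, -2.93 in upper hair follicle-like and -1.92 in sebaceous gland-like cells. With the 44 P7 and 164 adult cells below 3 G2/M UMIs alone it was -1.12.

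Of 22 measured interferon and antigen-presentation genes 18 were lower at P7 and 12 by 2-fold or more (median -1.21, percentile 0). The immunoproteasome subunit Psmb8 had 2.88 CPM at P7 and 24.2 in the adult, and Ifi27l2a, an interferon-inducible gene, 8.43 and 63.5. The proteasome activator subunits Psme2 and Psme1 were close between libraries, with log2 ratios of 0.25 and 0.21. The median was -0.01 in sebaceous gland-like cells, so the group was not lower there. Of 21 measured antioxidant and xenobiotic genes 13 were lower at P7 (median -0.65, percentile 0.01). The metallothioneins Mt1 (454 against 2358 CPM) and Mt2 (582 against 2479 CPM), which bind zinc and copper, lay lowest, while Gstm1, a glutathione transferase, and Prdx1, a peroxiredoxin, were higher at P7 with log2 ratios of 0.94 and 0.61. Of 20 measured immediate early genes, which respond to growth signals and to tissue dissociation, 16 were higher at P7 (median 0.61, percentile 99.9), but with transcript length subtracted the list lay within random lists (0.18, percentile 96.3). Among members at 20 CPM or more in either library, Ier5 (log2 2.13) and Jund (1.26) were highest, and Fosb (-1.51) and Dusp1 (-0.89) lowest.

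**Figure D2:**
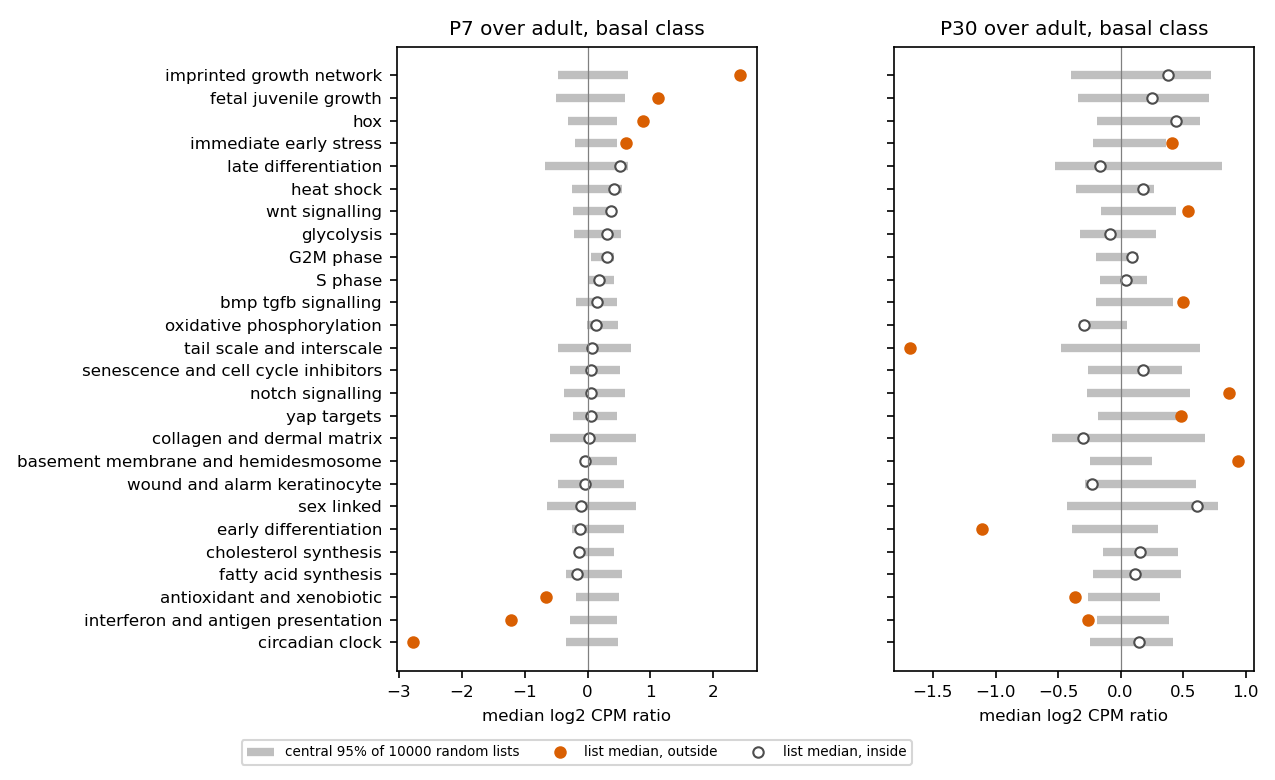
Median log2 CPM ratio of each fixed gene list, P7 over adult on the left and P30 over adult on the right, with bars spanning the central 95% of 10000 matched random lists. Points outside their bars include the imprinted growth network (2.43) and the circadian clock (-2.77) on the left, and the basement membrane list (0.94) and early differentiation list (-1.11) on the right.

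The other 19 lists lay within the central 95% of random lists for P7 over adult. Both cycle lists did so, S phase at 0.18 (percentile 33.2) and G2/M at 0.30 (percentile 70.0), although Pcna, the replication clamp (211 against 71.0 CPM), and Ube2c, a mitotic ubiquitin-conjugating enzyme (380 against 176 CPM), were higher at P7. Median log2 ratios were -0.04 for basement membrane and hemidesmosome genes, -0.12 for early and 0.51 for late differentiation genes. They were 0.42 for heat shock, -0.04 for wound and alarm keratinocyte, 0.31 for glycolysis and 0.13 for oxidative phosphorylation genes. Lipid synthesis lists stood at -0.14 for cholesterol and -0.17 for fatty acids. Signalling lists stood at 0.37 for Wnt, 0.05 for Notch, 0.15 for BMP and TGFβ, and 0.05 for YAP targets. The tail scale and interscale list stood at 0.06, sex-linked genes at -0.11, collagen and dermal matrix genes at 0.02, and senescence and cell cycle inhibitor genes at 0.06. Members of a list could still move far apart. Among early differentiation genes Krt1, a suprabasal keratin, was higher at P7 (1851 against 645 CPM), while Krtdap, another suprabasal gene, was lower (1116 against 7828 CPM). The lowest cluster had 736 and 416 CPM of Krt1, so free RNA could make up much of its values. For Krtdap free RNA was not separated from expression either. Among wound and alarm genes Krt17, a keratin of appendages and injured skin, was higher at P7 (1287 against 191 CPM, with 867 and 141 CPM in the lowest cluster), while S100a9 had 2 UMIs at P7 and 28.98 CPM in the adult, a log2 ratio of -8.93 (-11.98 to -7.07).

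Peg3 and H19 were highest at P7 of the named genes. Among the others of the 12 highest, Fst (ENSMUSG00000021765, chromosome 13, 114452290 to 114458951), the activin antagonist follistatin, had 181 CPM at P7 and 7.58 in the adult. With the libraries clustered together, Fst and Sostdc1 were among the leading genes of a cycling keratinocyte-like cluster of 507 P7 cells. Both also led adult cluster 2, which was upper hair follicle-like. For Fst the make-up of the class could therefore not be separated from age. Wnt6 (ENSMUSG00000033227, chromosome 1, 74771892 to 74785322), a Wnt ligand, had 136 and 7.55 CPM. Cxcl14, a chemokine, had 1409 and 166 CPM. Marcksl1 and Cald1, both binding actin, had 224 against 12.5 and 61.5 against 3.53 CPM. Krt7, a keratin of simple epithelia, had 229 and 15.98 CPM. Sult5a1, a sulfotransferase (113 against 4.35 CPM), Pglyrp4, a peptidoglycan recognition protein (71.4 against 5.75 CPM), and Klk10, a kallikrein-related peptidase (74.4 against 7.81 CPM), were also among the 12 highest. Ccer2, with 69.9 and 7.65 CPM, completed them. It is also the leading gene of the Merkel-like cluster of the P7 library, where it had 64192 CPM. In the P7 basal class 39.0% of cells had a UMI of Ccer2, and free RNA was not separated from expression there. The log2 ratio of Ccer2, 3.19, was 0.95 with doublets kept.

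Among the 12 lowest at P7, Krt24 (ENSMUSG00000020913, chromosome 11, 99279959 to 99285262) had 0.475 CPM at P7 (0.271 to 0.771) and 54.6 in the adult (52.0 to 57.3). Of its P7 UMIs 81.3% lay in 10 cells, and its log2 ratio of -6.85 was -7.94 (-9.82 to -6.58) among cells below 20 G2/M UMIs. Mt4 (ENSMUSG00000031757, chromosome 8, 94137197 to 94139031), a metallothionein of stratified epithelia, had 72.6 and 1729 CPM. The lowest adult cluster had 646 CPM of Mt4, so free RNA can make up part of the adult value. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, had 12.3 and 218 CPM. Hopx, an atypical homeodomain protein, had 6.23 and 120 CPM. Crip1, a LIM domain protein, had 42.3 and 719 CPM, Gpha2, a glycoprotein hormone subunit, 11.3 and 172 CPM, Dapl1 61.8 and 823 CPM, and Chit1, a chitinase, 3.18 and 52.6 CPM. The hair-type keratins Krt36 and Krt84, which mark tail scales, had 24.6 against 439 and 2.46 against 108 CPM. In the adult, however, the lowest value in any cluster was 400 CPM for Krt36 and 94.3 for Krt84, so free RNA could not be told from expression in the basal class. S100a8, a subunit of calprotectin, had 0.712 and 51.3 CPM, with 85.7% of its adult count in 10 cells. Its log2 ratio of -6.17 was -9.43 (-12.47 to -7.57) among cells below 20 G2/M UMIs and -9.47 (-12.52 to -7.62) in the basal-like clusters alone, each with 2 UMIs at P7, and -4.79 with all kept cells. Hist1h2ap (16.1 against 527 CPM) shares sequence with other histone genes and is reported as uncertain.

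**Figure D3:**
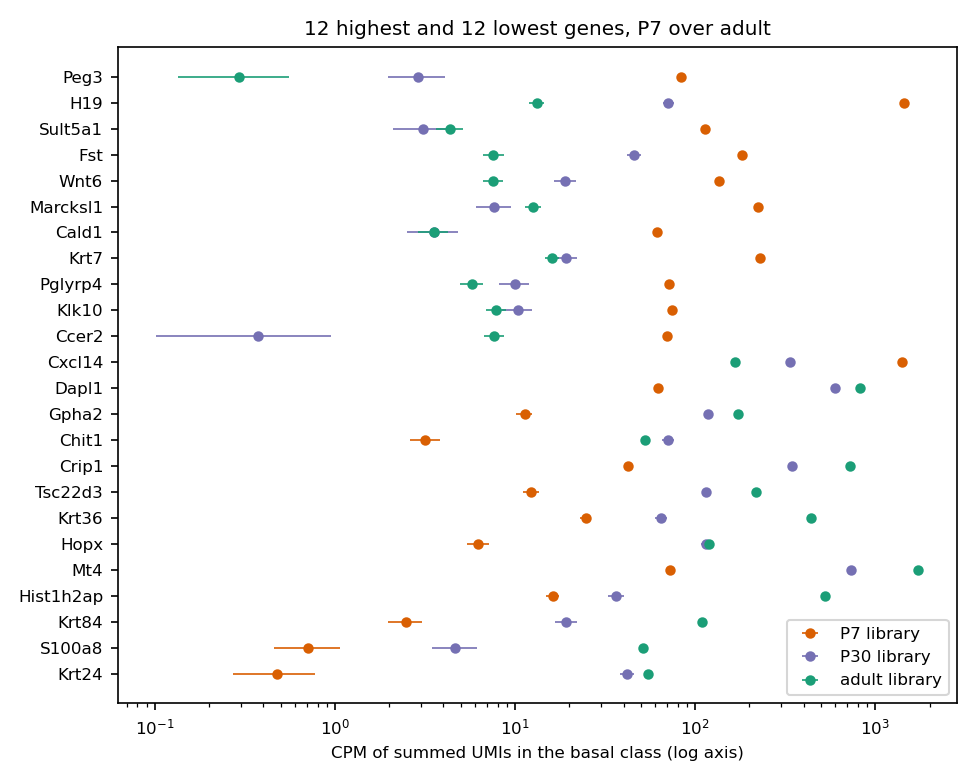
CPM in the basal class of each library (log axis) for the 12 highest and 12 lowest named genes of P7 over adult, with Poisson 95% intervals. H19 stands at 1451, 71.0 and 13.2 CPM in the P7, P30 and adult libraries, and Mt4 at 72.6, 732 and 1729 CPM.

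Ribosomal protein genes took 17.5% of UMIs in the P7 basal class, 26.2% at P30 and 25.5% in the adult, and mitochondrially encoded genes 3.29%, 6.64% and 2.96%. Transcript length went with the P7 to adult ratio. Protein-coding genes under 500 nt outside the ribosomal set had a median log2 ratio of -1.37 (49 genes), those of 500 to 800 nt -0.12 (295 genes), and those of 1200 to 2000 nt 0.52 (1466 genes). After the median of genes of like length was subtracted, the list medians were 1.84 for the imprinted, 0.97 for the fetal and juvenile, 0.49 for the Hox, -3.00 for the clock, -1.50 for the interferon and -0.50 for the antioxidant genes, and each still lay outside the central 95% of random lists. The immediate early list did not. Ratios of single genes, among them Mt1, Mt2 and Mt4, are given without this subtraction.

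**Figure D4:**
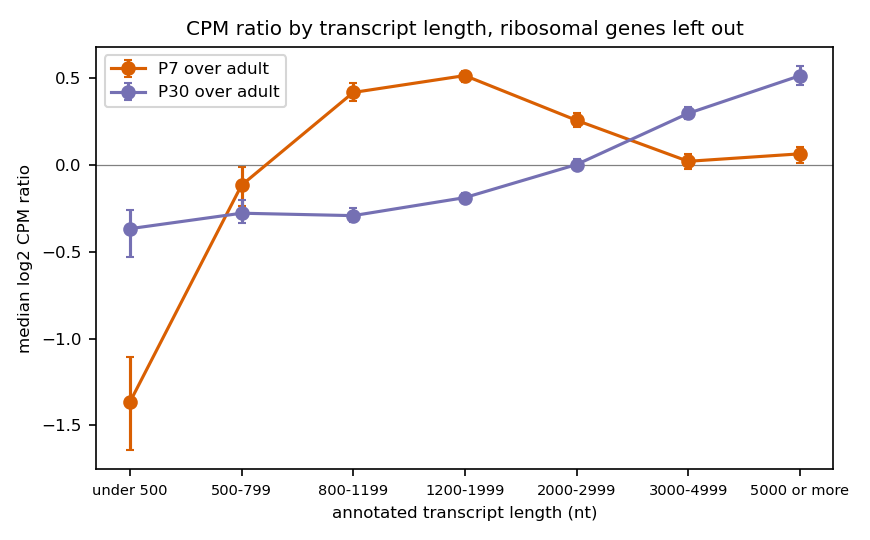
Median log2 CPM ratio, P7 over adult and P30 over adult, of protein-coding genes by annotated transcript length (nt), ribosomal protein genes left out, with 95% intervals of the median over genes. P7 over adult lies at -1.37 for the shortest genes and peaks at 0.52 between 1200 and 2000 nt, while P30 over adult goes from -0.37 for the shortest to 0.52 for the longest genes.

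The comparison of P30 with adult sets the intermediate age against the adult. Genes of the basement membrane and hemidesmosome, of BMP and TGFβ signalling, and immediate early genes were higher in the P30 library as groups. Early differentiation, tail scale and antioxidant genes were lower as groups. For keratins of the early differentiation and tail scale lists, however, adult values could not, or mostly not, be told from free RNA. The Notch, Wnt and YAP lists were higher and the interferon list lower before, but not after, transcript length was allowed for. The clock genes, so different between P7 and adult, lay within random lists (median 0.14, percentile 68.8). Of 5972 genes 661 were at least 2-fold apart, 485 higher and 176 lower at P30. The share higher was 73.4%, against 39.0% with TMM factors and 57.3% among genes at 100 CPM or more. The median log2 ratio over all genes was 0.03, against -0.21 with TMM and 0.12 without mitochondrial and ribosomal protein genes.

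Of 24 measured basement membrane and hemidesmosome genes 21 were higher at P30 and 11 by 2-fold or more (median 0.94, percentile 100). The type IV collagen chain Col4a5 had 54.2 against 10.8 CPM and Frem2, which anchors epidermis to dermis, 48.9 against 12.97 CPM. Lypd3 (50.2 against 162 CPM) and Fermt1 (67.7 against 107 CPM), the latter encoding the integrin activator kindlin-1, were lower. In the Notch list 8 of 11 genes were higher (median 0.87, percentile 99.9), with the ligand Jag2 at 126 against 51.2 CPM, although the target Hes1 was lower at 51.4 against 145 CPM. In the Wnt list 17 of 25 genes were higher (median 0.54, percentile 99.6), with Wnt4 at 437 against 154 and the receptor Fzd10 at 45.5 against 18.3 CPM. In the BMP and TGFβ list 16 of 20 were higher (median 0.50, percentile 99.2), including Fst (45.7 against 7.58 CPM) and the signal transducer Smad4 (65.9 against 15.8 CPM). Of 20 YAP target genes 15 were higher (median 0.49, percentile 98.5), led by Tead1, the DNA-binding partner of YAP (39.4 against 14.1 CPM). Of 20 immediate early genes 13 were higher (median 0.41, percentile 98.7), with Atf3 at 51.5 against 16.0 CPM. Mitochondrially encoded genes, a sign of cell stress, took 6.64% of UMIs at P30 against 2.96% in the adult beside all of these groups. With TMM factors the medians were 0.28 for the Wnt, 0.21 for the BMP and TGFβ, 0.25 for the YAP and 0.17 for the immediate early list. The P30 to adult ratio also went with transcript length, from a median of -0.37 for genes under 500 nt (49 genes) to 0.52 for those of 5000 nt or more (778 genes), and the median length was 6188.5 nt in the basement membrane list and 4593 nt in the Notch list. After the median of genes of like length was subtracted, the basement membrane list stood at 0.56 (percentile 100), the BMP and TGFβ list at 0.38 (percentile 99.4) and the immediate early list at 0.37 (percentile 99.6). The Wnt list at 0.29 (percentile 96.3), the Notch list at 0.35 (percentile 95.4) and the YAP targets at 0.17 (percentile 81.2) then lay within random lists. The Hox list, at 0.44 (percentile 97.7), lay above them. Genes of 5000 nt or more shared a bin without an upper limit, so any rise of the ratio beyond that length was not subtracted. The basement membrane list, with a median length of 6188.5 nt, may therefore keep part of the length trend.

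Of 14 measured early differentiation genes 11 were lower at P30 and 8 by 2-fold or more (median -1.11, percentile 0). The suprabasal keratins Krt10 (276 against 1327 CPM) and Krt2 (245 against 785 CPM) were lowest. The lowest adult cluster had 870 CPM of Krt10 and 546 of Krt2, so most of their adult values could not be told from free RNA. Of 7 tail scale and interscale genes 5 were lower (median -1.68, percentile 0), and that list shares Krt2 and Krt10 with the former. It also holds Krt36 and Krt84, whose adult values could not be told from free RNA either. The lower level of the tail scale list was therefore not separated from free RNA. Of 21 antioxidant and xenobiotic genes 14 were lower (median -0.37, percentile 0.24), with Gstm1 at 38.3 against 96.3 CPM, and of 24 interferon genes 18 were lower (median -0.26, percentile 0.58), with B2m, the light chain of class I molecules, at 90.1 against 366 CPM. With transcript length subtracted, the interferon list stood at -0.14 (percentile 6.96), within random lists, and the other 3 stayed outside. Within the clock list Per1 (50.5 against 24.1 CPM) and Nr1d2 (41.3 against 24.8 CPM) were higher, and Ciart (10.4 against 33.9 CPM) and Dbp (111 against 248 CPM) lower.

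The genes highest at P30 against the adult were Mbd2 (ENSMUSG00000024513, chromosome 18, 70568189 to 70626131), which binds methylated DNA, with 285 CPM at P30 (275 to 296) and 36.4 in the adult (34.3 to 38.6), and Hnrnpa0, an RNA-binding protein, with 363 and 49.8 CPM. They were followed by Lars2, a mitochondrial leucyl-tRNA synthetase (51.0 against 7.12 CPM), Ybx3, a cold shock domain protein (655 against 103 CPM), and Egln1, the oxygen-sensing prolyl hydroxylase (156 against 24.7 CPM). Baiap2l1 (58.97 against 10.6 CPM), H19 (71.0 against 13.2 CPM) and Rab21, a small GTPase (89.1 against 17.2 CPM), completed the 8. The first 5 of these had 29.4, 46.7, 6.53, 81.9 and 16.8 CPM at P7. With the libraries clustered together, all of the 8 but H19 were leading genes of the cluster that held 594 of the 654 P30 cells. They thus marked most of the P30 library and were not particular to its basal class. The P30 library also shared no barcode with the others and was sorted at another site, so age could not be separated from these differences. The lowest were Snhg9, a small nucleolar RNA host gene (0.65 against 64.4 CPM), Cst6, a cystatin (7.43 against 231 CPM), Sncg, a synuclein (4.36 against 119 CPM), S100a8 (4.64 against 51.3 CPM) and Krt36 (64.6 against 439 CPM). The log2 ratio of S100a8, -3.47, was reversed to 2.03 with doublets kept and to 2.94 among cells below 3 G2/M UMIs. Few cells carried the P30 values: all S100a8 UMIs lay in 9 of 297 cells, and 88.5% of Krt36 UMIs in 10 cells. Among cells below 20 G2/M UMIs the log2 ratio of Krt36, -2.77, was -5.67, and -6.17 below 3 UMIs, against -1.45 with all kept cells and -1.95 in the basal-like clusters alone. For Cst6 the lowest adult cluster stood at 228 CPM, so its adult value was close to free RNA. With all kept cells summed, its log2 ratio of -4.96 was -2.62. Tpm3-rs7 and Hist1h2ap were also among the 8 lowest and share sequence with near-identical copies, so they are reported as uncertain.

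The comparison of P30 with P7 sets the intermediate age against the earlier one. Clock genes were higher in the P30 library and imprinted, fetal and juvenile, and Hox genes lower as groups. Of 17 clock genes 16 were higher at P30 and 12 by 2-fold or more (median log2 ratio 2.67, percentile 100). Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333), the heme-binding clock repressor REV-ERBα, had 73.6 CPM at P30 (68.5 to 78.9), 5.34 at P7 (4.59 to 6.18) and 46.95 in the adult. Hlf, a clock output factor, had 65.7, 6.0 and 59.4 CPM in the same order. Of 10 imprinted growth genes 9 were lower at P30 and 7 by 2-fold or more (median -1.54, percentile 0). H19 had 71.0 CPM at P30 against 1451 at P7, and Peg3 2.88 against 83.9 CPM, with the smaller differences at Gnas (log2 -0.82) and Slc38a4 (-0.74). Fetal and juvenile genes had a median of -1.19 (7 of 10 lower, percentile 0) and Hox genes -0.90 (14 of 21 lower, percentile 0.03), although Hoxc13 (log2 1.45) and Hoxd11 (1.18) were higher at P30. This ratio too went with transcript length, but did not rise steadily with it. The median was 0.97 for genes under 500 nt (46 genes), -0.69 for those of 1200 to 2000 nt (1487 genes) and 0.59 for those of 5000 nt or more (797 genes). With length subtracted, the medians were 2.69 for the clock (percentile 100), -0.57 for the imprinted (percentile 1.53), -1.29 for the fetal and juvenile (percentile 0) and -0.42 for the Hox list (percentile 0.795).

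Basement membrane and hemidesmosome genes were higher at P30 than at P7 too, in 19 of 24 cases (median 1.05, percentile 100), with Col17a1, the hemidesmosomal collagen, at 1082 against 355 CPM. With length subtracted their median was 0.46 (percentile 99.7), again with all genes of 5000 nt or more in a shared bin. The remaining lists lay within random lists, but with length subtracted the interferon list, at 0.68 (percentile 95.6), was 0.85 (percentile 99.8) and the tail scale list, at -0.70 (percentile 8.24), was -1.07 (percentile 0.11). The genes highest at P30 were Cebpb, a transcription factor (104 against 1.90 CPM), Chit1 (70.6 against 3.18 CPM), Slc7a5, an amino acid transporter (53.9 against 2.70 CPM), Hopx (114 against 6.23 CPM), Hspa1b, the inducible HSP70 (53.2 against 4.19 CPM), Nr1d1, Hlf and the antisense transcript Epb41l4aos (81.3 against 7.45 CPM), reported as uncertain. The lowest were Ccer2 (0.371 against 69.9 CPM), Sult5a1 (3.06 against 113 CPM), Marcksl1 (7.62 against 224 CPM), Krt17 (63.6 against 1287 CPM), Tppp3, a tubulin-binding protein (6.13 against 111 CPM), Cald1 (3.53 against 61.5 CPM), Peg3 and H19. The P30 value of Ccer2 rests on 4 of 297 cells, so it depends strongly on which cells are kept. Its P7 value was not separated from free RNA of the Merkel-like cells, which were found at P7 only and had 64192 CPM of Ccer2. Of 6296 genes 1849 were at least 2-fold apart, 958 higher and 891 lower at P30. The share higher was 51.8%, against 38.6% with TMM factors, 77.7% without mitochondrial and ribosomal protein genes and 34.9% among genes at 100 CPM or more. The median log2 ratio over all genes was -0.18, against -0.29 and 0.06 under those 2 scalings.

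The authors' deposited regulon tables, analysed for P7 and adult, list transcription factors with their inferred targets. They hold 306 factors at P7 and 294 in the adult, of which 209 have a regulon in both, 97 at P7 alone and 85 in the adult alone. Of the 15 factors fixed beforehand 14 had a regulon in both libraries, and Irf7 in neither. The targets of a shared factor overlapped little, with a median Jaccard index of 0.0190 against 0.00292 for pairs of different factors. Of the 209 shared factors 58 lay above 0.0365, a value that 2.5% of the pairs of different factors exceeded. These pairs were not matched on the number of targets. Large target sets can overlap more by size alone, so part of this excess may reflect size. E2f1 (0.214) and E2f8 (0.213), both cell cycle regulators, Klf4 (0.1995), a factor of keratinocyte differentiation, and Grhl1 (0.188), a factor of epidermal barrier formation, shared the most among the fixed factors. Klf4 had 1939 targets at P7 and 1452 in the adult, and Trp63, the p63 gene required for stratified epithelia, 10 and 117.

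Within each library the activity score (AUC) separated differentiated-like from basal-like cells for the same Krüppel-like factors. The mean score of Klf4 was higher in differentiated-like cells by 2.94 SDs over cells at P7 and by 1.94 in the adult. Klf5 was higher by 2.58 and 1.68 SDs, and Klf3 by 2.49 and 1.73. Mta3 was 2.59 SDs higher at P7. Scores were lower in differentiated-like cells for Trp63 (-1.11 and -0.81 SDs) and Ezh2, a Polycomb methyltransferase (-1.96 and -1.45 SDs), and at P7 for Sox4 (-2.21) and Nfib (-2.13). Between cells above and below 20 G2/M UMIs Ybx1 differed most at P7 (2.79 SDs) and Rad21, a cohesin subunit, in the adult (3.49 SDs). Ctcf differed by 2.47 SDs at P7 and 3.25 in the adult, Nfyb by 2.14 and 3.37, and E2f8 by 1.92 and 2.93. Klf4 was lower in cells above it, by -1.17 SDs at P7 and -2.44 in the adult. At the fixed threshold of 3 UMIs, with 44 P7 and 164 adult cells below it, Ezh2 led at P7 (1.35 SDs) and Ybx1 in the adult (1.22 SDs). Differentiated-like cells were deeper than basal-like ones, with 8899 against 5999 median UMIs at P7 and 8641 against 6908 in the adult, so part of their contrast may come from depth. Cells above the threshold of 20 were deeper, with 8835 against 6219 median UMIs at P7 and 10477 against 6987 in the adult, and scores are not compared across libraries. In both contrasts the groups of cells and the scores were drawn from the same transcripts of the same cells. These separations therefore describe the libraries and give no independent evidence of a factor's activity.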

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

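The tests of ribosomal protein genes, of the hour of collection and of the barcode list were chosen only after their results were seen. Cells of types outside the keratinocyte comparisons appeared in a pair of libraries. They are noted because they passed the limit that a count of 0 allows, which any cluster of more than 3 cells passes. Merkel-like cells, led by Ccer2, Pou4f3 and Atoh1, numbered 38 at P7, which is 0.419% of cells (0.297 to 0.575) against a limit of 0.0331%. None were found at P30 or in the adult (0 cells each), where limits were 0.459% and 0.0315%. Melanocyte-like cells, led by Dct, Pmel and Tyrp1, numbered 15 in the adult, 0.157% of cells (0.0882 to 0.26) against a limit of 0.0315%, and 0 at P7 when each library was clustered alone. Clustered together, 5 P7 cells (0.0552%), 1 P30 cell and 15 adult cells were melanocyte-like.

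Ribosomal protein genes were lower in the P7 than in the adult basal class, 68 of 88 measured genes and 33 by 2-fold or more, with a median log2 ratio of -0.90 (-0.99 to -0.66). The set was mostly drawn by gene symbol, Rpl or Rps followed by a number. That pattern can also take in some kinases and other genes that are not ribosomal proteins, which may be among the 43 longer ones below. Scaling by the library total was argued against, since it moves all genes alike and the ribosomal protein genes lay -1.15 (-1.24 to -0.91) from the median of all other measured genes. Transcript length as the whole cause was argued against as well, since after subtraction of the median of other genes of like length -0.70 remained (-0.88 to -0.48). That short transcripts were captured less well at P7 stays open as part of the cause: 344 other genes under 800 nt had a median of -0.26 (-0.43 to -0.12), against 0.28 for 5269 longer genes, and the ribosomal protein genes were graded by length themselves, with -1.89 under 500 nt, -0.98 at 500 to 800 nt and -0.06 (-0.83 to 0.16) for the 43 longer ones. Age itself stays open and untested.

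The clock genes were lower at P7 than in the adult. A different make-up of the basal class was argued against, since the list median was -1.92 in sebaceous gland-like and -2.46 in differentiated-like cells; in upper hair follicle-like cells, which come from unlike clusters, it was -2.93. Transcript length was argued against too, since the median was -3.00 after subtraction of genes of like length. The hour of collection stays open and cannot be told apart from age, because the labels give no hours and the 2 measured genes that peak opposite to Dbp and the Per genes, of Arntl, Npas2 and Nfil3, were higher at P7 with a median of 1.40. Age stays open as the untested biological explanation.

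At P30 133 genes were at least 2-fold higher than in both other libraries and 40 were at least 2-fold lower. Damage that differs between the kept P30 cells was argued against. These 133 genes had a median log2 ratio of -0.0524 (-0.0831 to -0.00208) between P30 basal class cells above and below the median mitochondrial share of 6.59%. Damage or stress shared by the whole P30 library stays open, since a split within that library cannot show it. Mitochondrially encoded genes took 6.64% of UMIs in the P30 basal class, against 3.29% at P7 and 2.96% in the adult. The make-up of the basal class stays open, as 103 of the 133 genes (77.4%, 69.4 to 84.2) were 2-fold higher than in both others in differentiated-like cells too, and the bound set for excluding it lay within that interval. P30 and P7 shared 0 barcodes where 14.1 were expected, P30 and adult 0 where 14.9 were expected, and P7 and adult 162. Barcodes began with 480 different prefixes at P7 and in the adult, all of them shared, and with 597 at P30, 77 of them shared. These values go with a different barcode list for P30, although the labels name V2 chemistry for all ages. Whether other reagents raised the 133 genes stays open and cannot be told apart from age or site. Age stays open and untested here as well.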

How the results depend on the processing

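The lists with transcript length subtracted, the threshold of 20 UMIs, the cells below it, the basal-like clusters alone and the wide basal class were chosen only after the data were seen. No paired analysis was possible because each age has 1 library. Over 170 results and 1332 alternatives, 875 values stayed within their spread or 1.5 times their count and the others moved. Of all values, 81 changed sign: 79 medians of lists that lay within random lists, and 2 values of S100a8. A further 10 values of single genes, all among cells below 3 G2/M UMIs, rest on a count of 0 and give only a bound that allows the reported ratio, so they are left out. List medians from these cells include genes whose count of 0 was set to 3, which can make a ratio smaller. Each of the 7 lists outside random lists for P7 over adult and the 10 for P30 over adult kept its sign under all 11 alternatives run. For P30 over P7 only transcript length was tried, and 5 lists outside random lists kept their sign. Few cells were below 3 G2/M UMIs (44 P7, 33 P30 and 164 adult cells), since at these depths that threshold counts most cells, and the values from them are limited by it. Except where an alternative itself leaves fewer genes or cells, the cause was not tested.

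Counts of genes 2-fold apart at a floor of 100 CPM, which leaves fewer genes, were 295 for P7 with adult, 556 for P30 with P7 and 150 for P30 with adult. At 5 CPM they were 1539, 3028 and 1247. Among cells not in cycle they were 1636 for P7 with adult and 1115 for P30 with adult, and S100a8 was reversed to 2.94 for P30 over adult. With doublets kept, it was reversed to 2.03.

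List medians for P7 over adult moved as follows. The interferon list was -0.86 with 500 genes and 20% mitochondrial UMIs, -1.02 in all kept cells, -0.62 in cells not in cycle, -0.86 at a floor of 20 CPM and -1.50 with length subtracted. The clock list was -2.48 in basal-like clusters only, -2.50 in all kept cells, -2.45 below 20 cycle UMIs, -1.12 in cells not in cycle, -3.00 with length subtracted and -2.56 in the wide basal class. The fetal list was 0.63 in basal-like clusters only, 0.66 below 20 cycle UMIs and 0.56 at 20 CPM. The antioxidant list was -0.34 in all kept cells and -0.37 at 20 CPM. The immediate early list was 0.18 with length subtracted and 0.44 in the wide class, and length took the imprinted list to 1.84 and the Hox list to 0.49.

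For P30 over adult, TMM factors gave 0.69 for basement membrane, -1.35 for early differentiation, 0.17 for immediate early, -0.50 for interferon, 0.28 for Wnt, 0.63 for Notch, 0.21 for BMP and TGFβ, 0.25 for YAP, -2.21 for tail scale and -0.61 for antioxidant genes. Length subtracted gave 0.56 for basement membrane, -0.86 for early differentiation, 0.29 for Wnt, 0.35 for Notch and 0.17 for YAP, and for P30 over P7 0.46 for basement membrane, -0.57 for imprinted and -0.42 for Hox genes. All kept cells gave -0.88 for early differentiation, 0.70 for Wnt, 0.67 for BMP and TGFβ and -1.33 for tail scale. Cells not in cycle gave -0.80 for early differentiation, -0.77 for interferon, 0.20 for Wnt, 0.46 for Notch and -1.06 for tail scale. A floor of 20 CPM gave 0.52 for Notch, 0.19 for YAP and -1.97 for tail scale. Immediate early genes were 0.63 and tail scale genes -2.04 with 500 genes and 20% mitochondrial UMIs. Basal-like clusters only gave 0.57 for immediate early and -0.11 for interferon genes. Cells below 20 cycle UMIs gave 0.33 for BMP and TGFβ and -2.17 for tail scale, doublets kept -2.20 for tail scale, and the wide class -0.85 for early differentiation and -2.06 for tail scale.

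The basal class share was 48.9%, 41.3% and 36.2% at P7, P30 and adult with 500 genes and 20% mitochondrial UMIs, 53.2%, 37.2% and 33.7% with doublets kept, 58.3%, 91.3% and 44.7% under joint clustering, and 65.8% (P7) and 41.6% (adult) at Leiden 1.2. The differentiated-like share was 13.9% (P7) and 21.3% (adult) with 500 genes and 20% mitochondrial UMIs, 12.9%, 22.3% and 19.2% with doublets kept, 13.4%, 0.306% and 23.8% under joint clustering, and 19.3% (P30) and 24.6% (adult) at Leiden 1.2. The cycle share was 90.8%, 72.5% and 82.1% with the S-phase list, 92.9%, 65.4% and 80.5% at 5 UMIs, 38.1%, 32.5% and 30.0% at 20 UMIs, and 25.8%, 17.1% and 12.4% at 20 UMIs in all kept cells. It was 99.7%, 98.7% and 98.9% without thinning, 86.0%, 64.3% and 73.2% thinned to 2000 UMIs, 98.5% (P7) and 92.3% (adult) in all kept cells, and 92.2% (P30) with doublets kept. A Jaccard index of at least 0.2 left 6 shared factors.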

Other observations

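The glucocorticoid list was chosen after Tsc22d3 and the metallothioneins had been seen; its prediction was written before its value was computed. Sebaceous gland-like cells also held many G2/M transcripts. At 20 or more UMIs after thinning, 114 of 370 cells were counted at P7 (30.8%, 26.1 to 35.8), 8 of 17 at P30 (47.1%, 22.98 to 72.2) and 32 of 214 in the adult (14.95%, 10.5 to 20.4). Among the clusters without a name, cluster 12 of the P7 library stood apart with 58 cells (0.640%). It was led by Krt6b, a keratin of injured skin. Krt6a and the interferon-induced genes Bst2, Rtp4, Isg15 and Ifit1 were also among its leading genes. The interferon and antigen-presentation list was lower as a group in the P7 basal class, but not through these genes. In the wide basal class Isg15 had 5.66 CPM at P7 and 3.28 in the adult. Bst2, Rtp4 and Ifit1 were also slightly higher at P7 there, all at low CPM. Among the regulons of immediate early and growth factors, chosen after their sizes were seen, sizes differed in both directions. Fos had 601 targets at P7 and 103 in the adult, Jun 736 and 54, Junb 727 and 185, and Myc 306 and 22, but Egr1 had 42 and 69, Fosl1 138 and 179, and Fosl2 17 and 40. Regulon sizes come from separate inference in each library and are given as values only.

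Tsc22d3 and metallothionein transcripts were lower at P7 than in the adult, and a weaker glucocorticoid response at P7 may be a candidate explanation. The values of these genes were not corrected for transcript length, which went with the P7 to adult ratio. A list of 16 other glucocorticoid-responsive genes was tested, from which Klf9, seen before among leading genes of clusters, and Lcn2, a member of another list, had been removed beforehand. Of the 9 measured, 7 were lower at P7, with a median log2 ratio of -1.46 (percentile 0). The lowest, all chosen after their values were seen, were Fkbp5 (1.37 against 25.7 CPM, log2 -4.24), a chaperone of steroid receptors, Zbtb16 (-3.31) and Bcl6 (-2.87), while Cebpd (0.53) and Nfkbia (0.49) were higher at P7. Glucocorticoid levels follow the hour of day and handling, so the hour of collection, for which the opposite-phase clock genes gave 1.40, stays open beside age.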
